A study of Mus musculus with 9 samples.

How the data were processed

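RNA from cultured mouse granulosa cells was hybridised to Affymetrix mouse arrays, with 9 arrays in 3 groups of 3 named for the adenovirus used (GFP, Cre, WNT4). Groups and replicate numbers were taken from the labels. The deposited values are log2 expression values made with RMA, per the submitters' processing notes; the RMA version is not given in the sources used here. That they are on a log2 scale was read from the values, which run from 3.46 to 15.3. RMA corrects background, normalizes between arrays and summarises the probes of a set, so between-array differences in total signal are already reduced. No array scans were used here. No pair of arrays shared more than 4.53% exactly equal values, so no array was counted as a copy of another.

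The table held 45101 probe sets, of which 64 Affymetrix controls were left out and 45037 tested. Gene names came from the platform annotation paired with the probe sets: 34945 tested probe sets had 1 symbol, 932 had several and were not named, and 9160 are unnamed here. Symbols were updated by Entrez ID through a RefSeq gene table (assembly GRCm38.p6, used for names only), which matched 34741 of the 34945. This gave 18193 genes. Some genes of the fixed lists, such as Cyp19a1 and Lhcgr, are not analysed here. No coordinates are given, because no genome build is named for the probe sets.

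Linear models were fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 2.8 prior degrees of freedom), with no covariate, two-sided, and Benjamini-Hochberg adjustment over the 45037 probe sets of each comparison. A probe set was called at an adjusted p under 0.05. Errors after a difference are the model's standard errors, and errors after a mean are standard deviations. With 3 arrays against 3, an exact permutation test of a single value cannot go below p = 0.1, so single genes rest on limma's shared estimate of the spread.

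Gene lists were fixed before the data were examined, 20 in number: WNT and beta-catenin targets, WNT pathway parts (ligands and receptors included), steroidogenesis, cholesterol synthesis, granulosa and FSH response, LH response, luteal, Sertoli, theca with stroma and smooth muscle, leukocyte, oocyte, endothelial, ovarian surface epithelium, erythrocyte, interferon, p53 and DNA damage, cell cycle, unfolded protein, junctions and extracellular matrix. Each gene was read from its probe set with the highest mean over the 9 arrays. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 60 tests (20 lists in 3 comparisons). Of the 16 lists called, 0 held with an estimated correlation, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes, called 1 (the p53 list in WNT4 against GFP, adjusted p = 0.0129). Members were also adjusted over the list alone. Lists of hypoxia genes (27 measured) and of NF-kappaB inflammatory genes (31 measured) were written after the data were seen.

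The genes named in the report follow a rule fixed in advance. It took every probe set of Wnt4 and Ctnnb1, up to 10 called genes each way by size of change (5 for WNT4 against Cre) with the arrays of the groups fully separated, up to 4 members of each list with the lowest p, and a set of ovarian and WNT genes in both comparisons with GFP. Genes outside it are marked as chosen after their values were seen.

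Alternatives were the replicate number as a block, a fit of the arrays of each pair alone, quantile normalization, centring on the median or the 75th percentile, leaving out probe sets with a mean under 6, an intensity trend in eBayes, array weights, other thresholds, 1 probe set per gene, the mean of a gene's probe sets, and leaving out each array in turn. A pair of further fits, without the 3 arrays numbered 3 and without Cre 3 and WNT4 3, was chosen after seeing the data.

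The labels do not say that a replicate number marks a shared animal or day. Deviations from the group means of same-numbered arrays correlated, across probe sets, at 0.21, 0.24 and 0.77 between Cre and WNT4, at -0.04, -0.31 and 0.31 between GFP and Cre, and at -0.08, 0.01 and 0.35 between GFP and WNT4. By the rule that every pair exceeds 0.1, the numbers were taken to pair the samples in WNT4 against Cre alone, from the data and not from the labels. Deviations cancel within a group, so the 0.77 of the arrays numbered 3 pushes pairs of arrays numbered 1 and 2 towards positive values. Cre 1 with WNT4 2 (0.28) and Cre 2 with WNT4 1 (0.32) exceeded the 0.21 and 0.24 of the same-numbered pairs. The rule therefore cannot show that numbers 1 and 2 are paired. In WNT4 against Cre the block gave 0 called probe sets and 7 called lists, against 5 without it.

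The overlap of both comparisons with GFP was set beside 100 simulations of unchanged groups that share the controls. The procedure was tested on simulated data for WNT4 against GFP with 45037 probe sets: 73 of 100 probe sets changed by 1 on the log2 scale and 98 of 100 changed by 2 were recovered, and 8 unchanged ones were among the 179 called. A list raised by 0.5 was called, and 0 of 19 unchanged lists were. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.803. The simulation therefore does not check list calls among correlated genes. The recovered shares do not give the power for real genes either. The changed probe sets were drawn at random, and their own number eases the Benjamini-Hochberg threshold. In the real data Nt5e, chosen after its values were seen, differed by 3.43 ± 0.44 between WNT4 and GFP and was not called (limma adjusted p = 0.0691).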

Results

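Gene expression was measured in cultured mouse granulosa cells, the follicle cells that surround the oocyte, on 9 Affymetrix mouse arrays. The cells were taken from mice 20 to 26 days old, 48 h after equine chorionic gonadotrophin, a hormone that drives follicle growth. They were then infected for 24 h with an adenovirus carrying enhanced GFP (the control), Cre recombinase or WNT4, with 3 arrays per virus and a nominal multiplicity of infection of about 50 throughout. Cre recombines floxed alleles of Ctnnb1, the gene of beta-catenin, which carries canonical WNT signals into the nucleus. Which genotype each group of cells had, and whether the recombined allele removes or stabilises beta-catenin, is not given in the sources used here. The RMA values ran from 3.46 to 15.3 on the log2 scale, with array medians of 5.44 to 5.54. The number of arrays limits the precision. The labels call the replicates biological and say nothing of separate animals or cultures, so p-values measure the spread between these samples.

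The target genes were read first, and they did not settle the labels. Wnt4, a secreted WNT ligand, averaged 9.41 ± 0.46 (SD, n = 3) with GFP, 10.63 ± 0.55 on the arrays labelled Cre and 9.34 ± 0.48 on those labelled WNT4 (the Wnt4 probe set with the higher mean over all arrays, log2). The array with the highest value of this probe set, 11.25, was a Cre array. The other Wnt4 probe set averaged 8.32 ± 0.78, 9.62 ± 0.51 and 9.29 ± 0.82 in the same order. Ctnnb1 was not lower on the arrays labelled Cre: its 3 probe sets differed from GFP by 0.04 ± 0.21, 0.10 ± 0.23 and 0.20 ± 0.24 (SE). On the arrays labelled WNT4 they differed from GFP by 0.53, 0.48 and 0.53, or 0.05, 0.35 and 0.31 after quantile normalization. None of these differences passed limma's test over all probe sets. Whether the Wnt4 probe sets lie within the transcript made by the virus, or the Ctnnb1 probe sets within the deleted part, is unknown here, and a probe set outside would check nothing. Directions below are therefore given for the arrays as labelled.

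**Figure D1:**
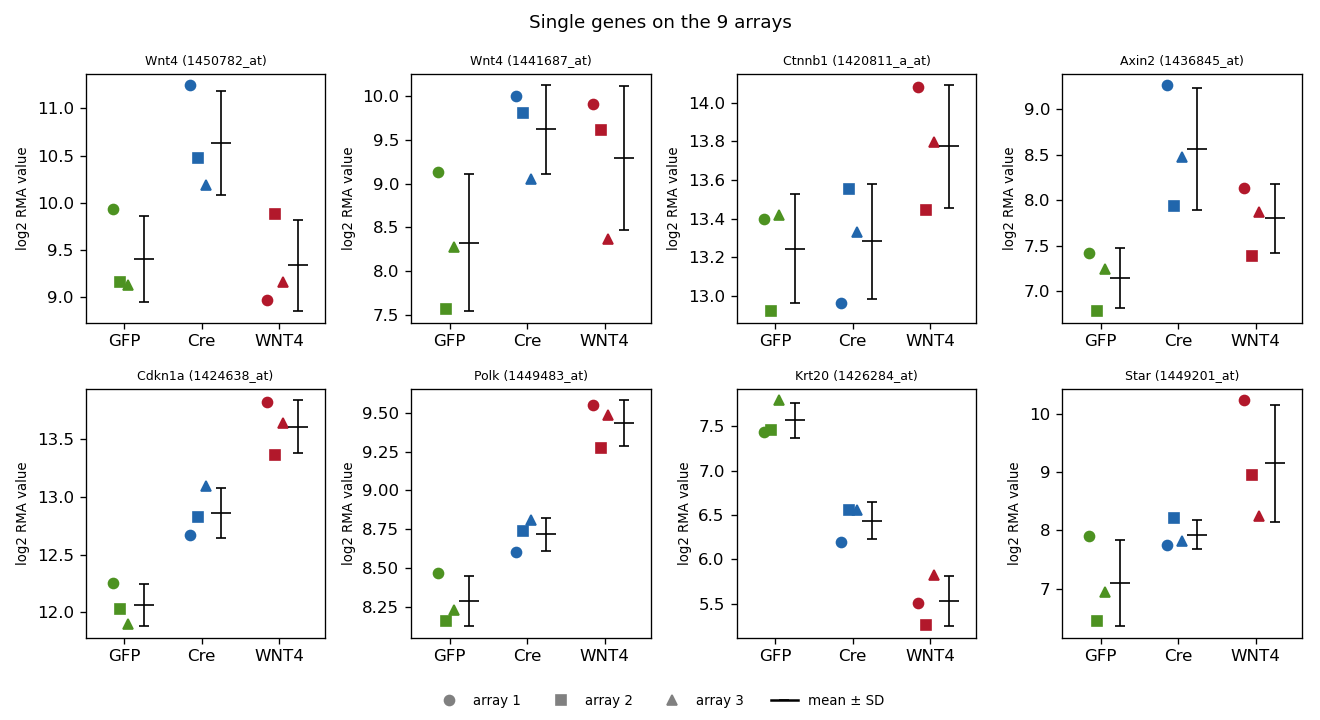
Log2 RMA value (vertical axis) of 8 probe sets on the 3 arrays of each virus group (horizontal axis), 1 point per array, with the mean ± SD in black. Wnt4 (upper left) is highest on the arrays labelled Cre (mean 10.63), while Cdkn1a and Polk are highest and Krt20 lowest on those labelled WNT4 (means 13.61, 9.44 and 5.53).

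Cells labelled WNT4 were compared with GFP to find the genes that differ between these virus groups. Cdkn1a, which encodes the cell cycle inhibitor p21 and is a classical p53 target, rose 2.92-fold (log2 1.55 ± 0.16, SE, n = 3 arrays per group). Polk, a DNA polymerase that copies past damaged bases, rose 2.21-fold (1.15 ± 0.12), and Ak1, an adenylate kinase that balances ATP and AMP, rose 2.30-fold (1.20 ± 0.11). Mapkapk3, a kinase acting downstream of p38, rose by 0.85 ± 0.08, with its other probe set at 0.47. Exoc4, a part of the exocyst that tethers secretory vesicles, rose by 0.98 ± 0.10, although its 4 probe sets with a mean of at least 6 spread from -0.15 to 0.98. Krt20, an intermediate filament keratin of epithelial cells, fell by 2.04 ± 0.17 on the log2 scale. These genes and an unnamed probe set (1.40 ± 0.14) were the 7 called among 45037 by limma, each at adjusted p = 0.0341, and for each all 3 arrays of a group lay on the same side of all 3 arrays of the other. The calls lay close to the threshold: leaving out GFP 2, GFP 3, WNT4 1, WNT4 3 or any single Cre array gave 0 calls, leaving out GFP 1 gave 9, and leaving out WNT4 2 gave 748, of which 683 were higher. With the replicate number as a block 10 were called, among them Ak1, Exoc4, Krt20 and the other probe set of Cdkn1a (1.88), and with an intensity trend Krt20 alone was.

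Beyond these calls the arrays labelled WNT4 differed broadly from GFP. At an unadjusted p under 0.05, 5870 probe sets differed, 4109 higher and 1761 lower, where 2251.8 would be found by chance. The groups did not overlap at 6655 probe sets (14.8%), where chance gives 10%. The share of higher values among the 5870 was 70% and followed the scaling: it was 48.0% after quantile normalization, 80.1% after median centring and 30.1% after centring on the 75th percentile, which moved the median of all probe sets to -0.15. Under quantile normalization 3 probe sets were called, Krt20 and the unnamed probe set among them, and with the arrays of these groups alone 0 were.

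Stress programmes stood out among the gene lists fixed in advance, all higher on the arrays labelled WNT4. Of 19 measured genes of the p53 and DNA damage response, 16 rose and 3 did not pass when adjusted over the list alone, with Cdkn1a and Polk also called over all probe sets. Among them were Btg2, an antiproliferative p53 target (1.54 ± 0.21), and Mdm2, the ligase that degrades p53 (0.98 ± 0.16). The list's median change was 0.84, or 1.79-fold (camera adjusted p = 2.11e-13; adjusted p = 0.202 with an estimated correlation), and it was the only list of any comparison that fry, a test of the list alone, called as well (adjusted p = 0.0129). Of 17 genes of the unfolded protein and integrated stress response, 15 rose when adjusted over the list alone and 0 of them over all probe sets. These included Ddit3, the stress transcription factor CHOP (2.69 ± 0.55), Herpud1, a part of endoplasmic reticulum-associated degradation (2.24 ± 0.46), and Hspa5, the chaperone BiP (1.21 ± 0.31, with probe sets from 0.26 to 1.48). The median of this list was 1.53 (camera adjusted p = 2.8e-10; adjusted p = 0.551 with an estimated correlation). Array WNT4 1 carried much of it: the list stood 2.45 above the GFP mean there, 0.49 on WNT4 2 and 1.43 on WNT4 3, and without WNT4 1 its median was 1.03. That array also had the highest 3' to 5' differences of all 9 (1.38 for beta-actin, 2.17 for Gapdh), the highest upper quartile and the lowest array weight (0.67).

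Interferon and antiviral genes formed the remaining stress list. Of 27 measured members, 12 rose, 1 fell and 14 did not pass when adjusted over the list alone, and 0 were called over all probe sets. Ifih1, a sensor of double-stranded RNA, rose by 1.72 ± 0.36, Rsad2, the antiviral protein viperin, by 3.04 ± 0.69, and Usp18, which restrains interferon signalling, by 3.09 ± 0.74. Zbp1, a sensor of Z-form nucleic acid, fell by 0.61 ± 0.13. The list's median was 1.08 (camera adjusted p = 3.28e-05; adjusted p = 0.61 with an estimated correlation). Without WNT4 1 the median was 0.45, and with the mean of all probe sets of each gene it was 0.57. The list stood 1.33, 0.21 and 0.65 above the GFP mean on WNT4 1, 2 and 3, and 0.37 above it on Cre 3. The list of leukocyte markers, whose cells express many interferon genes, had a median of -0.04 (camera adjusted p = 0.269). All calls of these lists held under each of the scalings tried.

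**Figure D2:**
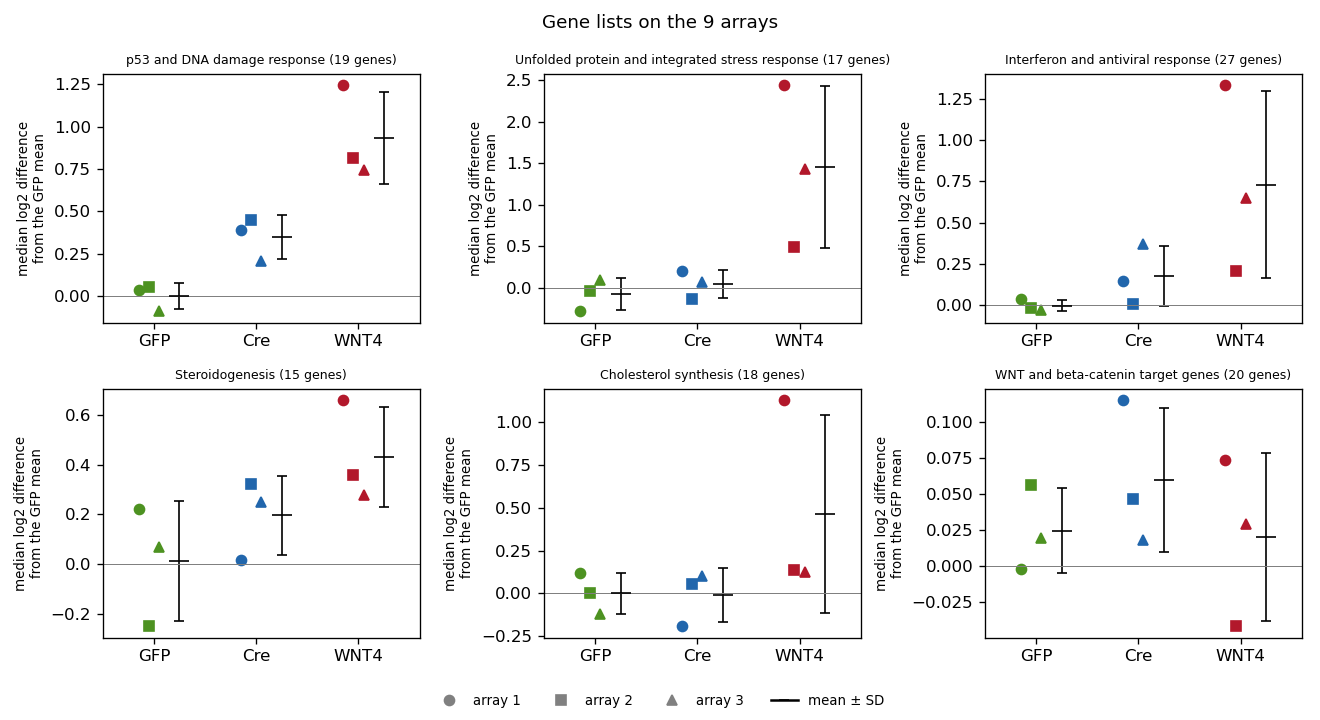
Median log2 difference from the mean of the GFP arrays (vertical axis) over the measured genes of 6 lists, 1 point per array, with the mean ± SD of each virus group (horizontal axis) in black. The p53 list stands at 0.74 to 1.25 on the arrays labelled WNT4 and at 0.21 to 0.45 on those labelled Cre, and the unfolded protein list reaches 2.45 on WNT4 1.

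Genes of steroid hormone production also had a higher list median on the arrays labelled WNT4 than with GFP. Relative to the GFP mean the list stood at 0.66, 0.36 and 0.28 on WNT4 1, 2 and 3. It stood at 0.22, -0.25 and 0.07 on the GFP arrays and at 0.02, 0.32 and 0.25 on the Cre arrays in the same order. WNT4 2 and WNT4 3 thus lay close to Cre 2 and Cre 3. Without GFP 2 the list's median change was 0.34, with the call kept. Adjusted over the list alone, 6 of 15 steroidogenesis genes rose, 9 did not pass, and 0 were called over all probe sets. Star, which moves cholesterol into mitochondria for steroid synthesis, rose 4.15-fold (2.05 ± 0.50), and Cyp11a1, the enzyme that cleaves the cholesterol side chain, rose 2.31-fold (1.21 ± 0.41). Scarb1, the receptor that takes up cholesterol from high-density lipoprotein, rose by 1.10 ± 0.24, and Fdx1, the electron carrier of mitochondrial steroid enzymes, by 0.82 ± 0.21. The list's median was 0.46 (camera adjusted p = 0.00978; adjusted p = 0.61 with an estimated correlation), and the call was lost after quantile normalization (median 0.21, camera adjusted p = 0.0897) and when dim probe sets were left out (adjusted p = 0.127).

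Cholesterol synthesis genes had a median of 0.41 (camera adjusted p = 0.00883; adjusted p = 0.816 with an estimated correlation), but 0 of 18 members passed over the list alone. Lss, lanosterol synthase, differed by 0.86 ± 0.30 and Sqle, squalene epoxidase, by 0.68 ± 0.26. This list rested on WNT4 1, where it stood 1.13 above GFP, and without that array its median was 0.08 with no call. It was also lost without GFP 3 (median 0.35), after quantile normalization (0.17) and when dim probe sets were left out (0.41), and kept at 0.26 after centring on the 75th percentile.

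Genes of the LH response and of luteal cells were called as well. In the LH list 4 of 21 genes rose over the list alone: Cebpb (0.99 ± 0.17) and Cebpa (0.64 ± 0.13), transcription factors needed for luteinization, Adamts1 (1.24 ± 0.31), a matrix protease of ovulation, and Timp1 (0.71 ± 0.19), an inhibitor of matrix proteases. Its median was 0.20 (camera adjusted p = 0.0437; adjusted p = 0.392 with an estimated correlation). That call was lost without GFP 3 (median 0.27), without WNT4 2 (0.28) and without WNT4 3 (0.24), after median centring (0.25) and when dim probe sets were left out (0.39). It was also lost without the arrays numbered 3 (0.21) and without Cre 3 and WNT4 3 (0.24), fits chosen after seeing the data, and was kept at 0.05 after centring on the 75th percentile. In the luteal list 2 of 10 genes rose over the list alone, Cdkn1a and Parm1, an androgen-regulated membrane glycoprotein (0.97 ± 0.12). The luteal median was 0.59 (camera adjusted p = 0.0425; adjusted p = 0.604 with an estimated correlation), and the call was lost without GFP 2 (median 0.23), GFP 3 (0.71) or WNT4 2 (0.51), with the replicate number as a block (0.59), after quantile normalization (0.34), after median centring (0.63) and when dim probe sets were left out (0.65). Vegfa, an angiogenic factor and hypoxia target on that list, differed by 2.05 ± 0.95, and a list of 27 hypoxia genes written after the data were seen stood 2.98 above GFP on WNT4 3 and 2.51 on Cre 3.

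The remaining 13 lists gave no camera call for WNT4 against GFP (adjusted p from 0.198 to 0.914). Granulosa and FSH response genes had a median of 0.04, a mean of -0.10 and a test pointing down, which became a call after quantile normalization (median -0.25), without WNT4 1 (-0.17) and when dim probe sets were left out. In that list Bmpr1b, a receptor of bone morphogenetic proteins, fell by 1.56 ± 0.29 over the list alone. Esr2, the oestrogen receptor of granulosa cells, differed by -1.25 ± 0.36 and Foxl2, which maintains granulosa identity, by -0.32 ± 0.11, neither passing. Fshr, the FSH receptor (0.06 ± 0.28), Fst, an activin-binding protein (-0.14 ± 0.14, with its other probe set at 0.27), Inhba, an activin subunit (-0.11 ± 0.19), and Sox9, the Sertoli cell determinant (-0.01 ± 0.13), did not pass either. WNT and beta-catenin target genes had a median of 0.05 and WNT ligands, receptors and pathway parts a median of 0.04. In the target list Apcdd1, a WNT inhibitor, rose by 1.08 ± 0.24 over the list alone (its probe sets spread from -0.06 to 1.41), while Axin2, a feedback inhibitor induced by beta-catenin, differed by 0.65 ± 0.33 and Lef1, a partner of beta-catenin, by -0.04 ± 0.11 (Lef1 and Sox9 are dim, with means under 6). In the extracellular matrix and TGF-beta list (median 0.18) Thbs1, an antiangiogenic matrix protein, fell by 1.72 ± 0.47, Lamb1, a laminin chain, fell by 0.51 ± 0.15, and Sparc, a collagen-binding protein, rose by 0.74 ± 0.14 with probe sets from -0.49 to 0.74, all over the list alone. Among cell-cell junction genes (median 0.10) Nectin2, an adhesion receptor, rose by 0.88 ± 0.15 over the list alone.

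Markers of other cells were measured beside these lists. Their medians for WNT4 against GFP were 0.46 for the oocyte, -0.06 for Sertoli cells, 0.03 for theca, stroma and smooth muscle, 0.05 for endothelium, 0.07 for the ovarian surface epithelium and -0.13 for erythrocytes. Cell cycle genes had a median of -0.14, which changed with the array left out: it was -0.56 without GFP 1 and -0.53 without WNT4 1, called lower both times, and 0.05 without GFP 2 and 0.02 without WNT4 2. The spread ran across the groups. Relative to the GFP mean the list was low on GFP 1, Cre 2 and WNT4 2 (-0.69, -0.45 and -0.65). It was high on GFP 2, Cre 1 and WNT4 1 (0.55, 0.33 and 0.42). These sets cross the replicate numbers, and whether they share a culture or batch was not tested. For the theca, endothelial and surface epithelial lists the test, which compares a list with all other genes, pointed down while the median lay above 0. The oocyte genes stood 1.27 above the GFP mean on WNT4 1, 0.09 on WNT4 2 and -0.04 on WNT4 3, and GFP 2 itself stood at 0.49. The theca and stroma list stood at 0.32, -0.14 and -0.14 on these arrays. Among its members, chosen after their values were seen, Dcn, the matrix proteoglycan decorin, read 9.50 on WNT4 1 and 6.51 and 6.45 on the others (GFP 6.57 to 6.64). Lum, the proteoglycan lumican, read 7.33, 4.68 and 4.65 (GFP 4.71 to 4.91), and Pdgfra, a growth factor receptor of stromal cells, 8.16, 5.84 and 6.64 (GFP 5.67 to 6.48).

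Cells labelled Cre were compared with GFP, a contrast that holds Cre expression itself beside any recombination of Ctnnb1. Recombination was not shown on these arrays, so the cause of the differences stays open. The p53 and DNA damage response rose here too: 6 of 19 genes passed over the list alone, 0 fell and 13 did not pass. Cdkn1a rose by 0.80 ± 0.16, Btg2 by 0.82 ± 0.21, Mdm2 by 0.54 ± 0.16 and Polk by 0.43 ± 0.12 (SE, n = 3 arrays per group). The list's median was 0.43 (camera adjusted p = 7.78e-13; adjusted p = 0.202 with an estimated correlation), and 0.28 without GFP 3. Axin2 rose 2.67-fold over the list of WNT and beta-catenin targets alone (1.41 ± 0.33, adjusted p = 0.0455), from 7.15 ± 0.33 with GFP to 8.56 ± 0.67 (SD). The other 19 of 20 target genes did not pass, Bambi, a decoy receptor induced by WNT signals, at 1.28 ± 0.38 and Apcdd1 at 0.65 ± 0.24. That list's median was 0.15 (camera adjusted p = 0.00122; adjusted p = 0.202 with an estimated correlation), and it was 0.07 without Cre 1, 0.10 without Cre 3 and 0.23 without GFP 3, 0.30 without dim probe sets and 0.08 with the mean of each gene's probe sets, with the call kept each time. The target list did not separate the arrays, however. Relative to the GFP mean it stood at 0.115, 0.046 and 0.018 on Cre 1, 2 and 3. On GFP 1, 2 and 3 it stood at -0.002, 0.056 and 0.020. Of its genes 13 were higher and 7 lower, and its mean change was 0.31. Fzd1, a WNT receptor, differed by 1.32 ± 0.29 and did not pass over its list (WNT ligands, receptors and pathway parts, median 0.03).

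Luteal and oocyte lists were called higher on the arrays labelled Cre as well. In the luteal list 1 of 10 genes rose over the list alone, Cdkn1a, which is also on the p53 list. Vegfa, the hypoxia target on that list, differed by 1.35 ± 0.95 and read 10.47 on Cre 3 against 7.25 and 7.43 on Cre 1 and Cre 2. The luteal median was 0.23 (camera adjusted p = 0.0202; adjusted p = 0.551 with an estimated correlation). The call was lost without GFP 2 (median 0.05), GFP 3 (0.25) or Cre 2 (0.07), after quantile normalization (0.15) and, in fits chosen after seeing the data, without the arrays numbered 3 (0.21) or without Cre 3 and WNT4 3 (0.17). It was kept at medians of 0.45 without GFP 1 and 0.46 without Cre 1, at 0.37 with array weights and at 0.35 when dim probe sets were left out. Oocyte markers had a median of 0.35 with 0 of 15 members passing (camera adjusted p = 0.0133; adjusted p = 0.816 with an estimated correlation). Gdf9, an oocyte growth factor, differed by 0.53 ± 0.52 and Oosp1, an oocyte-secreted protein, by 0.70 ± 0.62. This call was lost without Cre 1 (median 0.12), GFP 1 (0.28) or GFP 3 (0.19) and with array weights (0.22), and was kept without GFP 2 (0.62), without Cre 3 (0.57) and without Cre 3 and WNT4 3 (0.57).

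The other 16 lists gave no call for Cre against GFP (camera adjusted p from 0.0518 to 0.985). Interferon genes had a median of 0.24, steroidogenesis genes 0.18, unfolded protein genes 0.06, cholesterol synthesis genes 0.00 and granulosa genes -0.09. Star differed by 0.83 ± 0.50, Cyp11a1 by 0.30 ± 0.41, Bmpr1b by -0.86 ± 0.29 and Foxl2 by -0.28 ± 0.11. Fshr (-0.09 ± 0.28), Fst (0.01 ± 0.14), Inhba (-0.08 ± 0.19), Lef1 (-0.01 ± 0.11) and Sox9 (0.07 ± 0.13) lay within 1 SE of GFP. Over all probe sets limma called 0, with 1006 at an unadjusted p under 0.05 (455 higher and 551 lower, 45.2% higher), below the 2251.8 found by chance. Median centring put the higher share at 63.7%. The groups did not overlap at 2712 probe sets (6.02%), where chance gives 10%. Without GFP 1 a single probe set was called, that of Gm15866, a predicted gene chosen after its values were seen (-1.75 ± 0.61 with all arrays).

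Cells labelled WNT4 were compared with those labelled Cre, a pair that does not share the GFP arrays. The unfolded protein response had the largest list median between them: 11 of 17 genes rose on the arrays labelled WNT4 when adjusted over the list alone, and 6 did not pass. Herpud1 rose by 2.17 ± 0.46, Ddit3 by 2.33 ± 0.55, Creld2, a chaperone-like protein of the endoplasmic reticulum, by 2.26 ± 0.54 and Hspa5 by 1.25 ± 0.31. The median was 1.28 (camera adjusted p = 1.06e-13; adjusted p = 0.501 with an estimated correlation), and 0.91 without WNT4 1. In the p53 list 4 of 19 genes rose over the list alone, Polk (0.72 ± 0.12), Cdkn1a (0.74 ± 0.16), Btg2 (0.72 ± 0.21) and Aen, a nuclease induced by p53 (0.69 ± 0.16). Its median was 0.45 (camera adjusted p = 4.06e-09; adjusted p = 0.313 with an estimated correlation).

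Interferon genes had a median of 0.50 between these groups with 0 of 27 passing (camera adjusted p = 3.4e-05; adjusted p = 0.61 with an estimated correlation); the median was 0.29 without WNT4 1, 0.82 without Cre 3, 0.80 when dim probe sets were left out and 0.80 without the arrays numbered 3 or without Cre 3 and WNT4 3. Cholesterol synthesis genes had a median of 0.39 with 0 of 18 passing (camera adjusted p = 0.000174; adjusted p = 0.61 with an estimated correlation), which was 0.20 after quantile normalization and, without WNT4 1, 0.05 with no call. Steroidogenesis genes had a median of 0.27 with 0 of 15 passing (camera adjusted p = 0.0202; adjusted p = 0.61 with an estimated correlation). That call was lost without WNT4 1 (median 0.16), WNT4 2 (0.40) or Cre 1 (0.22), after quantile normalization (0.11) and when dim probe sets were left out (0.27), and was kept without Cre 3 (0.41) and after centring on the 75th percentile (0.16). The other 15 lists were not called (adjusted p from 0.0695 to 0.819). Without WNT4 1, 6 of these lists were called, and without Cre 2, 3 were. Parm1 (0.62 ± 0.12) and Cdkn1a rose over the luteal list alone. With the replicate number as a block, the LH response (median 0.19, adjusted p = 0.0426) and the WNT targets (median -0.03, adjusted p = 0.0425) were called in addition; with an estimated correlation and no block neither was (adjusted p = 0.46 and 0.501). Axin2 differed by -0.76 ± 0.33 and Wnt4 by -1.30 ± 0.34 (the probe set with the higher mean), neither passing. The other Wnt4 probe set differed less, at 9.91, 9.62 and 8.36 on the arrays labelled WNT4 and 10.01, 9.81 and 9.05 on those labelled Cre. Over all probe sets limma called 0 (lowest adjusted p = 0.773), with 2808 at an unadjusted p under 0.05, 81.3% of them higher on the arrays labelled WNT4. That share was 49.5% after quantile normalization and 49.4% after centring on the 75th percentile. The groups did not overlap at 3706 probe sets (8.23%), where chance gives 10%.

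The responses on the arrays labelled WNT4 and Cre were set against each other over all probe sets. No probe set was called by limma in both comparisons with GFP, and at an unadjusted p under 0.05, 319 were higher in both, 285 lower in both and 0 opposite. Sharing the GFP arrays favours changes in the same direction, and these counts were not simulated. The log2 changes correlated at r = 0.724 across probe sets, which are not independent replicates, at 0.578 without WNT4 3, and at 0.648 without Cre 3 and WNT4 3, a fit chosen after seeing the data. Unchanged groups simulated against shared controls, with all arrays of each group, gave 0.503. That value is a reference for the 0.724 only. The fits that leave arrays out were not simulated, so 0.578 and 0.648 cannot be compared with 0.503. The covariance was 0.0385 against 0.0220 simulated, a difference of 0.0165, and the highest of 100 draws gave 0.0238. The simulation contains the shared GFP arrays but not the joint deviation of Cre 3 and WNT4 3, which raises the covariance, so how much of the excess is a shared response stays open.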

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

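Among the tests in this part, only that of array scaling for the stress genes was set before its result was seen; all the others were chosen only after the result was seen. The tests of leukocyte markers, of array scaling for Cre 3 and WNT4 3 and of a condition shared equally by the arrays numbered 3 replaced earlier versions that had already been run.

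Control probe sets, left out of every comparison, carried signal above the controls. Of 51 with a mean of at least 6, 7 were higher on all 3 arrays labelled WNT4 than on any GFP array, where chance gives 5%, and 0 were on those labelled Cre. The differences from GFP (log2) were 0.533 for 18S ribosomal RNA, 0.546, 0.486 and 0.434 for the 3', 5' and middle probe sets of beta-actin, 0.864 and 0.952 for the 3' and middle probe sets of Gapdh, and 0.547 for the B2 repeat. They come from 4 transcripts or repeats and are bright, and the 10506 probe sets with a mean of at least 8 stood 0.24 higher as well (-0.01 after quantile normalization).

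The p53, unfolded protein and interferon genes stood higher on the arrays labelled WNT4, with list medians of 0.84, 1.53 and 1.08. After quantile normalization the smallest excess of these medians over the upper limit of 10000 expression-matched random lists was 0.538. This argues against array scaling as the whole cause. Leaving out each WNT4 array, the smallest excess was 0.364, which argues against a single array as the whole cause. The interferon list was uneven, however, at 1.33, 0.21 and 0.65 on WNT4 1, 2 and 3. WNT4 2 lay below Cre 3 (0.37), so a rise on all arrays labelled WNT4 beyond those labelled Cre is not shown for that list. More leukocytes in the cultures would raise their markers together. The 8 markers with a mean of at least 6 had a median change of -0.0644 (SD 0.813 between markers), the most abundant being Laptm5 (-2.12 ± 0.66, other probe sets up to 0.48) and Lyz2 (-0.04 ± 0.42). That median plus 1 SD, 0.749, lay below the interferon median but above its 0.45 without WNT4 1. The SD leans on Laptm5, since the other markers ran only from -0.33 (Tyrobp) to 0.44 (Cd14). A rise of all leukocytes by the full interferon median is thus argued against. A smaller rise or a change in their state stays open. As a hypothesis, the genes may answer to this virus or to what it made the cells express. The nominal dose was the same for all arrays, but the dose reached and the health of each culture were not tested and stay open. So do RNA quality on WNT4 1 (3' to 5' differences of 1.38 for beta-actin and 2.17 for Gapdh, the highest of all arrays) and stromal cells or oocytes there. The oocyte list stood 1.27 above the GFP mean on that array. The p53 genes were also higher on the arrays labelled Cre.

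Wnt4 and Axin2 were highest on the arrays labelled Cre. Leaving out each Cre array, the smallest change from GFP of Axin2 and the Wnt4 probe set with the higher mean was 0.92, with all 3 Cre arrays above all 3 GFP arrays. This argues against a single array as the cause of their rise over GFP. For the other Wnt4 probe set the smallest change was 1.11, but the lowest Cre array (9.05) lay under the highest GFP array (9.13), so a single array stays open there. Leaving out a Cre array was not tested against the arrays labelled WNT4. There Axin2 overlapped, at 9.27, 7.94 and 8.47 on Cre and 8.14, 7.39 and 7.87 on WNT4, so a single array stays open for that difference. An exchange of the Cre and WNT4 labels cannot be told apart from a response: the Cre probe sets stood 0.197 higher over the other hybridisation spikes on the arrays labelled WNT4 (exact permutation p = 0.4, the lowest possible being 0.1), and cre RNA is spiked into every array, which would mask vector RNA, while the Ctnnb1 probe sets were lower than GFP on the arrays of neither label (0.04 to 0.20 for Cre, 0.48 to 0.53 for WNT4). Genotype and the kind of recombined Ctnnb1 allele, which could itself raise Axin2, are untested and stay open.

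Arrays Cre 3 and WNT4 3 deviated together: 27 hypoxia genes, listed because such genes stood out, were 2.51 and 2.42 above the other arrays of their own groups (list medians), and 25 of the 27 were at least 2-fold higher on both. Array scaling is argued against, since after quantile normalization their deviations still correlated at 0.766 across all probe sets, against at most 0.353 for the other 8 pairs of Cre and WNT4 arrays. A condition shared equally by all 3 arrays numbered 3 is argued against for the hypoxia genes, since 0 of them were 2-fold higher on GFP 3, but it stays open for the inflammatory genes, of which 6 of 31 were 2-fold higher on GFP 3 and 15 on both other arrays. Over all 18193 genes, 54 were at least 2-fold higher on GFP 3 and 227 on both Cre 3 and WNT4 3. A weaker shared shift stays open too. On GFP 3 the hypoxia median was 0.22 (upper limit of matched lists 0.19) and the inflammatory median 0.18 (upper limit 0.08). Deviations of GFP 3 correlated at 0.305 with Cre 3 and 0.347 with WNT4 3. Of 17 leukocyte markers, 3 were at least 2-fold higher on GFP 3 and 3 on both Cre 3 and WNT4 3. Their list medians there were 0.12, 0.19 and 0.16. Csf1r, Cd68, Ptprc, Adgre1, Cd14 and Fcer1g were highest on the array numbered 3 of every group, while Lyz2, Tyrobp, Laptm5 and the remaining markers were not. A leukocyte difference common to these arrays was not tested and stays open. The Gapdh 3' to 5' difference was 0.95 on Cre 3 and 1.36 on WNT4 3 against 1.77 to 2.17 on the other arrays, but that of beta-actin (1.07 and 1.30) lay within their 0.98 to 1.38, so unequal RNA degradation and low oxygen in these cultures stay open.

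Other splits of the 6 arrays of each pair were counted, and 10 splits are too few for a share under 0.05. For WNT4 against GFP, the real split called 7 probe sets and the highest other 0 (1 of 10 splits reached the real count), while 7 lists stood against a highest other of 8 (5 of 10). For Cre against GFP, 0 probe sets stood against 0 (10 of 10) and 4 lists against 9 (5 of 10). For WNT4 against Cre, 0 probe sets stood against 0 (10 of 10) and 5 lists against 12 (7 of 10). At an unadjusted p under 0.05 the real splits gave 5870, 1006 and 2808 probe sets, counts reached by 2, 7 and 6 of the 10 splits, with the highest others at 7151, 5189 and 4675. Among the 4 splits that part all 3 same-numbered pairs, the highest other gave 1812, 1833 and 2975 probe sets and 8, 9 and 5 lists.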

How the results depend on the processing

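The fits without the arrays numbered 3, and without Cre 3 and WNT4 3, were chosen only after the result was seen; the other alternatives were set before. For WNT4 against GFP, the 7 called probe sets became 0 with the arrays of the pair alone, 0 at an adjusted p under 0.01, 0 without the arrays numbered 3 and 0 without Cre 3 and WNT4 3. They became 1 with an intensity trend (Krt20), 3 after quantile normalization (2 of the 7 among them), 17 after centring on the 75th percentile (5), 15 without dim probe sets (all 7) and 17 with 1 probe set per gene. The stricter threshold removes calls by construction; for the rest the cause was not tested. Leaving out each array gave 0 to 748 for WNT4 against GFP, 0 to 1 for Cre against GFP, 0 throughout for WNT4 against Cre and 0 to 1 for the overlap. The 748 came without WNT4 2 and held all 7; 9 came without GFP 1 and held 3. Leaving out each array, the count of limma at an unadjusted p under 0.05 ranged from 3486 to 7578 for WNT4 against GFP.

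The 16 list calls became 0 with an estimated correlation and 1 with fry, and 12 to 23 leaving out each array. With the replicate number as a block, 10, 0 and 0 probe sets were called (3 of the 7 shared) and 19 lists. Of single lists it ended the luteal call for WNT4 against GFP and added interferon and junctions for Cre against GFP and the LH and WNT target lists for WNT4 against Cre, and it changed no other list call. Of 9 arrays, 3 correlated best with an array of their own number.

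Of 6746 values of single genes under the alternatives, including genes chosen after their values were seen, 6443 kept side and direction, 78 lost and 39 gained a call, 0 reversed and 186 changed sign while called in neither. Of 1317 list values, 1186 were unchanged in call, 67 lost, 64 gained and 0 reversed. The correlation of the responses ranged from 0.578 to 0.788 leaving out each array. Dim probe sets, whose signal may lie close to the background, may limit what could be called. Leaving them out moved the calls from 7 to 15 for WNT4 against GFP and left 0 for Cre against GFP and WNT4 against Cre.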

Other observations

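The genes in this part were chosen after their values were seen, and limma's test over all probe sets called none of them (lowest adjusted p = 0.0691). Between WNT4 and GFP, Tap1, which carries peptides into the endoplasmic reticulum, differed by 1.36 ± 0.20, and B2m, the light chain of class I molecules, by 1.37 ± 0.24 (SE, n = 3). On the arrays labelled Cre they stood at 0.58 ± 0.20 and 0.59 ± 0.24. Klf4, a transcription factor of growth arrest, differed by 2.55 ± 0.51 and 1.28 ± 0.51, with its other probe set at 1.84 and 0.41.

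Among larger differences, Nt5e, the ectoenzyme that makes adenosine from AMP, stood 3.43 ± 0.44 higher on the arrays labelled WNT4 than with GFP and 2.09 ± 0.44 higher on those labelled Cre. Its further probe set differed by 0.02 and -0.05. Tmem229a, a membrane protein, differed by 2.91 ± 0.38 and 1.57 ± 0.38, with its probe sets spread down to -0.09 and -0.07. Both genes were called for WNT4 against GFP with the replicate number as a block, without dim probe sets, after centring on the 75th percentile and without WNT4 2. Lower values were seen for Igf1, a growth factor made by granulosa cells, at -1.85 ± 0.33 and -0.44 ± 0.33. Fgd5, a regulator of Cdc42, differed by -1.92 ± 0.42 and -1.48 ± 0.42.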
